A study of Homo sapiens with 12 samples.

How the data were processed

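Poly(A) RNA was selected from total RNA and made into libraries with a NEBNext Ultra kit, per the labels, for A549, HCT116 and MHCC97H cells left untreated or treated with 1 µM TSA, 50 µM GSK126 or 100 µM S2101. A549 and MHCC97H were grown in DMEM and HCT116 in RPMI, per the labels, so medium and line cannot be told apart. Treatment times and vehicle controls are not given in the sources used here. The 12 libraries form 4 conditions of 3, each condition with 1 library of each line.

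The authors deposited 1 table per library with a raw read count per gene symbol, per the file headers. The same tables hold RPKM values that the authors computed per kilobase of the longest transcript, per the file headers. The RPKM values imply a library total that is 0.18 to 0.223% above the sum of the listed counts, checked on genes with at least 50 reads. Genome builds GRCh38 and hg38 are named in the submitters' processing notes. The aligner, the counter, its handling of strand and its handling of reads shared between genes are not given in the sources used here, so antisense and overlapping genes and members of multigene families are reported as uncertain.

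The tables list 25648 genes, of which 25647 occur in all 12 and were used; ZZZ3, which 1 table lacks, was left out. An entry that names no gene, present once in 11 of the 12 files, was left out of totals and tests. A spreadsheet had turned 26 symbols into dates, and 25 were renamed from the tables' own transcript accessions. RefSeq annotation of GRCh38.p14 matched 24952 genes (97.3%) by the transcript accessions listed with each gene. It gave coordinates and gene classes, with 18845 genes classed as protein coding. Library totals ran from 14468304 to 19061367 counts. No pair of libraries of one line agreed within sampling noise: the lowest chi-square per gene was 10.98, between the GSK126 and S2101 libraries of MHCC97H. Of the genes, 28.1 to 30.3% were at 0 in the untreated libraries and 22.2 to 23.3% under TSA.

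The test of single genes was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling (factors 0.889 to 1.118) and filterByExpr, which kept 16929 genes. All 12 libraries entered 1 model with condition and cell line as terms, leaving 6 residual degrees of freedom. The cell line pairs a treated library with the untreated library of the same line, since the labels give each line 1 library per condition. The common biological coefficient of variation was 0.296 and the median prior degrees of freedom 3.32. Calls are Benjamini-Hochberg adjusted p under 0.05. The 6 contrasts were each compound against untreated and each pair of compounds. P-values here rest on a spread between lines that all 4 conditions share, not on a spread between repeat cultures of a line.

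Gene lists were tested with fry (limma 3.58.1) in the same design, adjusted over the lists of a contrast. Fry asks whether a list moves, on balance, in one direction and does not compare it with other genes. Camera was run with a preset correlation of 0.01 and with an estimated one. Of 42 lists, 39 had at least 3 tested members; beta-defensins, the PRAME family and the late cornified envelope and SPRR genes had fewer and were only counted. Members were counted over all genes and adjusted over the list alone.

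Detected genes had at least 1 CPM of the library total. Switched-on genes had under 0.1 CPM untreated and at least 1 CPM treated in the same line. Changes within a line are log2 ratios of TMM-scaled CPM plus a pseudocount of 1. CPM levels given with a test are TMM-scaled, and those of detected genes, switched-on genes, lineage markers and the low-level comparison in A549 use library totals. A fold against a condition with 0 reads in all 3 libraries is given over a floor of 3 reads for the group. Differences in detected genes were tested with an exact sign-flip permutation test.

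The design, the lists, the settings to be varied and the rule for named genes were fixed before the data were examined. The rule took, per compound, the 10 largest increases and decreases among called genes that moved one way in all 3 lines and had a mean of at least 2 CPM in the higher condition. It added HDAC1, HDAC2, HDAC3, EZH2, KDM1A and CDKN1A, and up to 4 called members of each list, or the 2 with the largest change where none was called. It also took up to 5 switched-on genes per compound, the 3 largest increases and decreases per line and compound with at least 10 CPM in the higher library, and up to 4 lineage markers per list. Genes outside the rule are said to be so where they are named. Genes that could tell a person's sex were left out.

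Alternatives were RLE size factors, no filter on low counts, a filter of at least 10 CPM in 3 libraries, no cell line term, leaving out each line, a fit on the 6 libraries compared, and DESeq2 1.42.0. Further fits, chosen after the data were seen, left out the TSA libraries (9 libraries), the A549 S2101 library, or both (8 libraries). Shared untreated libraries were modelled with 20 simulations of unchanged groups. The 10 ways of dividing the 6 libraries of a contrast into groups of 3 were refitted. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

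The gene test was tested on simulated data with 100 genes changed by each fold. For TSA against untreated, with the spread of the 12 libraries and 16894 genes, it recovered 15% of 2-fold and 71% of 4-fold changes, with 8 false among 94 calls. For GSK126 against untreated, with the spread of the 9 libraries without TSA and 16768 genes, it recovered 67 and 97%, with 17 false among 181 calls. In both simulations the share of false calls was above the 0.05 aimed at. Far fewer genes were changed in them than the 5851 called under TSA. Adjusted p-values depend on how many genes change, so the recovered shares do not carry over to the real contrasts.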

Results

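RNA from 3 human carcinoma lines was sequenced in 12 libraries. A549 is a lung adenocarcinoma line, HCT116 a colorectal carcinoma line, and MHCC97H a line derived from a hepatocellular carcinoma. Each line was left untreated or treated with 1 µM trichostatin A (TSA), an inhibitor of histone deacetylases, 50 µM GSK126, an inhibitor of the histone methyltransferase EZH2, or 100 µM S2101, an inhibitor of the histone demethylase LSD1 (gene KDM1A). The series set out to find genes, and then proteins, that are not seen in untreated cells but become detectable after such treatments. Each line contributed 1 library per condition, so the replicates of a condition are the 3 cell lines (n = 3). P-values set a change against a spread between lines that is estimated over all 12 libraries together. They do not measure how far the change under one compound recurred, and a gene that moved mostly in 1 line can pass. The libraries held 14468304 to 19061367 gene counts, and 3 reads corresponded to 0.157 to 0.207 CPM (counts scaled to library size), a floor that covers counting error only. MALAT1, a nuclear long non-coding RNA, took 0.43, 0.3 and 0.2% of the counts in untreated MHCC97H, A549 and HCT116, and more in each treated library: 0.81, 1.12 and 0.8% under TSA, 0.46, 0.71 and 0.57% under GSK126 and 0.49, 0.5 and 0.43% under S2101. In the same order of lines, RNA28S5 took 1.74, 1.24 and 1.26% untreated and 1.99, 1.52 and 1.92% under TSA. The MTRNR2L genes took 0.48, 1.33 and 1.0% untreated and 0.69, 1.74 and 1.68% under TSA. Neither share rose in every GSK126 and S2101 library.

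TSA raised the number of detectable genes in each of the 3 lines. At a threshold of 1 CPM, untreated MHCC97H, A549 and HCT116 had 13099, 13564 and 13854 detected genes, and the TSA libraries 14646, 15157 and 14939. The gain was 1547, 1593 and 1085 genes, or 1408.3 ± 281.0 (SD, n = 3), of which 1143.7 ± 297.7 carry a protein-coding annotation. GSK126 added 296, 518 and 5 genes (273.0 ± 257.3) and S2101 188, 569 and 155 (304.0 ± 230.1). At 5 CPM the mean gain under TSA was 725.3 genes. The gain of HCT116 under GSK126 turned to -207 at 0.1 CPM, to -66 at 5 CPM and to -19 with libraries thinned to one total, and the mean under GSK126 was 159.7 at 0.1 CPM. Without A549 the mean was 150.5 under GSK126 and 171.5 under S2101. The gain of A549 under S2101 was 302 once a share of 7.72% of the TSA profile of that line was subtracted. A sign-flip permutation test over 3 lines gave exact 2-sided p = 0.25 for each compound, the smallest value that 3 pairs allow.

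**Figure D1:**
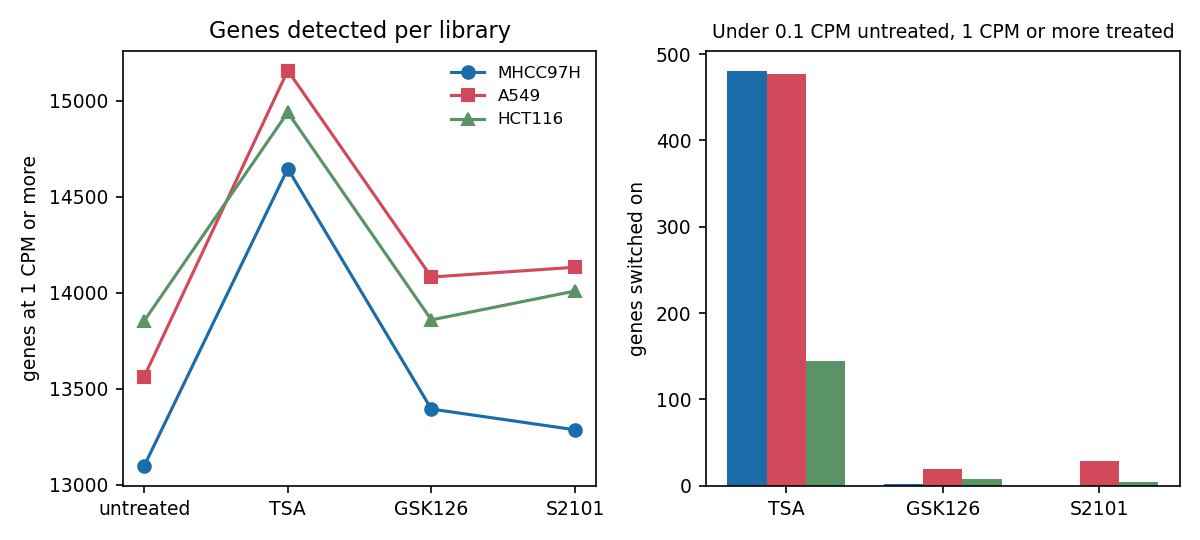
Genes at or above 1 CPM per library (left, vertical axis) by condition (horizontal axis), 1 point per library with MHCC97H in blue, A549 in red and HCT116 in green, and genes switched on per line (right, vertical axis) by compound. The TSA libraries lie at 14646, 15157 and 14939 against 13099, 13564 and 13854 untreated, and the bars under TSA at 480, 477 and 144.

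Genes switched on, defined as under 0.1 CPM in the untreated library and at least 1 CPM after treatment, numbered 480 in MHCC97H, 477 in A549 and 144 in HCT116 under TSA. The reverse change was seen for 12, 10 and 0 genes. GSK126 switched on 2, 19 and 8 genes and S2101 0, 29 and 4 genes in the same order of lines. Over the 3 lines, 932 genes were switched on by TSA in at least 1 line and 14 in all 3, and each of the 14 is annotated as protein coding. RFPL4A, a RING finger gene on chromosome 19 (positions 55757294 to 55763421 of GRCh38), had 2 reads in the 3 untreated libraries together and reached 24.5 ± 7.72 CPM (SD, n = 3) under TSA. Its counts are uncertain because a near-identical neighbouring copy exists. CEACAM20, a member of the carcinoembryonic antigen family (chromosome 19, 44506159 to 44529675), reached 20.7 ± 22.2 CPM, with 45.1 CPM in A549 and 1.95 CPM in HCT116. FABP4, the adipocyte fatty acid binding protein (chromosome 8, 81478419 to 81483233), had 0 reads in the untreated libraries and 20.2, 2.16 and 1.68 CPM under TSA in MHCC97H, A549 and HCT116. GPR50, a relative of the melatonin receptors on the X chromosome (151176584 to 151182856), reached 11.6 ± 13.8 CPM, and ACTBL2, an actin-like gene on chromosome 5 (57480018 to 57482811), 6.58 ± 4.01 CPM. The set was completed by ACTN2, ADCYAP1R1, ALOX15B, COL14A1, KRTAP3-1, PLCL1, SCN1A, STMN4 and TTC29, named here outside the fixed rule. A line-by-line count was not tested because each line has 1 library per condition. Leaving out MHCC97H, A549 or HCT116 gave 42, 31 or 110 genes switched on in all the remaining lines.

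Gene families whose proteins are often hard to find were counted separately. Clustered protocadherins, neuronal adhesion receptors encoded in tandem on chromosome 5, went from 14, 18 and 6 detected members of 52 in untreated MHCC97H, A549 and HCT116 to 28, 39 and 14 under TSA. Keratin-associated proteins, structural proteins of hair, went from 0, 0 and 0 of 93 to 2, 1 and 5. Cancer-testis genes went from 12, 7 and 5 of 40 to 16, 12 and 7. Olfactory receptors stood at 3, 1 and 12 of 379 untreated and 2, 2 and 11 under TSA, while those with at least 1 read went from 20, 21 and 40 to 40, 53 and 65 (25, 24 and 41 under GSK126, and 25, 40 and 53 under S2101). Taste receptors had 1, 1 and 3 detected members of 28 untreated and 1, 0 and 1 under TSA. Of 38 beta-defensins, 1, 0 and 0 were detected both untreated and under TSA, and of 21 PRAME family genes 0 were detected in each of the 12 libraries, with 1, 1 and 1 holding a read untreated and 7, 6 and 10 under TSA. The late cornified envelope and SPRR genes had 0 detected members of 29 in the untreated lines and 1 in HCT116 under TSA. Members of these families share reads with close copies, so the values of single members are uncertain.

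TSA changed the expression of a large part of the measured transcriptome. The largest increases were in genes with little or no signal in untreated cells, and genes of DNA replication and cell division were among those that fell. DHRS2, a dehydrogenase on chromosome 14 (23630115 to 23645639), went from 9.45 ± 9.91 to 1530 ± 1330 normalised CPM (SD, n = 3), a log2 change of 7.23 ± 1.1 (SE, adjusted p = 0.00261). SLC7A11, the cystine transporter on chromosome 4 (138164097 to 138242349), fell from 585 ± 319 to 60.7 ± 28.7 CPM, a log2 change of -3.16 ± 0.27 (adjusted p = 0.00111). Without A549 the adjusted p was 0.0374 for DHRS2 and 0.0577 for SLC7A11. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5851 of 16929 genes passed an adjusted p of 0.05, 2947 higher and 2904 lower. Of these, 5528 (94.5%) moved in one direction in all 3 lines, against 54.8% of all 16929 genes tested. Genes were called on the change over these same 3 lines, which favours one direction. The share of 94.5% is therefore no separate check of agreement between lines. The median absolute log2 change of the called genes was 1.24. At least a 4-fold change was seen for 1273 of the higher genes and 228 of the lower genes.

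Among genes with 0 reads in all 3 untreated libraries, CCNA1, the germ-cell cyclin A1, was at least 139-fold higher under TSA over a floor of 3 reads for the group, and FABP4 at least 127-fold. ACTBL2 was at least 105-fold higher, DPEP2, a dipeptidase, at least 87.3-fold, and CCND2, cyclin D2, at least 85.1-fold. PLCL1 was at least 74.7-fold and ZSCAN23, a zinc finger gene, at least 51.6-fold higher. A549 carried several of these bounds, with CCNA1 at 0.133, 22.9 and 0.662 CPM under TSA in MHCC97H, A549 and HCT116, DPEP2 at 0.331, 13.9 and 0.662, CCND2 at 2.85, 11.6 and 0.301 and ZSCAN23 at 0.0663, 7.15 and 1.56. Without A549 these 4 genes fell under the low-count filter and were not tested, and the adjusted p was 0.0609 for FABP4, 0.0679 for ACTBL2 and 0.0813 for PLCL1. Without MHCC97H the adjusted p of CCND2 was 0.0526. Among called genes that moved one way in all 3 lines with a mean of at least 2 CPM in the higher condition, the other 3 of the 10 largest increases were CEACAM20 (log2 change 9.41 ± 1.45), RFPL4A (9.13 ± 1.29) and RPL3L, a muscle form of a ribosomal protein (8.88 ± 1.18). By the same rule the largest decreases were in NUPR1, a stress-response gene (-3.45 ± 0.58), TYMS, thymidylate synthase (-3.43 ± 0.42), the transporter ABCC3 (-3.42 ± 0.41) and DHRS3 (-3.33 ± 0.63). SLC6A9, KCTD15, HTR1D, GBP3 and EPS8L3 lay between -3.18 and -3.13, beside SLC7A11. These calls had adjusted p of 0.0197 or less in edgeR's quasi-likelihood test. Of the genes in this paragraph, RFPL4A alone kept its call without A549 (adjusted p = 0.0374). Without MHCC97H, DHRS3, HTR1D, KCTD15 and GBP3 (log2 change -1.7) also lost theirs and EPS8L3 was not tested, nor was ZSCAN23 without HCT116. CEACAM20 stood at a log2 change of 7.29 without A549 and 12.33 without HCT116.

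Genes known to respond to histone deacetylase inhibitors rose together under TSA, with 13 of 16 listed members higher and none lower. Their median log2 change was 2.15 (fry adjusted p = 0.00086, adjusted p = 0.15 with an estimated correlation; 13 members passed adjusted over the list alone). TXNIP, a thioredoxin-binding protein (chromosome 1, 145992435 to 145996579), had a log2 change of 6.28 ± 0.98, with 4.73 in MHCC97H, 7.69 in A549 and 0.08 in HCT116. HIST2H2BE, a histone H2B gene (chromosome 1, 149884459 to 149886682), went from 3.20 ± 2.30 to 84.5 ± 62.3 CPM, and MT1X, a metallothionein, rose by 5.12 ± 1.05. Histone genes rose as a group, with 40 of 54 higher and 3 lower, and a median log2 change of 3.03 (adjusted p = 0.0031, adjusted p = 0.33 with an estimated correlation; 41 higher and 3 lower adjusted over the list alone). HIST1H1B (5.70 ± 1.04), HIST1H4I (4.85 ± 1.08) and HIST1H3H (4.58 ± 0.54) had the largest changes among those that passed. On ratios within a line, with a pseudocount of 1, the histone median was 0.6, 1.75 and 0.88 in MHCC97H, A549 and HCT116, below the fitted 3.03. The libraries were made from poly(A) RNA, which holds canonical histone transcripts only where they are polyadenylated, and histone copies can share reads. Of the metallothioneins, metal-binding proteins encoded together on chromosome 16, 5 of 6 rose, with a median of 3.6 (adjusted p = 0.036, adjusted p = 0.46 with an estimated correlation; 6 adjusted over the list alone). MT2A went from 127 ± 142 to 690 ± 565 CPM, and MT1G (4.93) and MT1A (2.93) also passed. Without A549 the histone list stood at adjusted p = 0.064 and the metallothioneins at 0.24, and the latter stood at 0.1 without HCT116, whereas the responders stood at 0.031 without A549. Of the genes in this paragraph, HIST2H2BE alone kept its call without A549 (adjusted p = 0.0374), where TXNIP stood at 0.0593. Without MHCC97H, HIST1H1B and MT1A (log2 change 1.22) lost theirs. There HIST1H4I stood at 7.43, MT1X at 3.47, MT1G at 3.28 and MT2A at 2.31, the last from 3.71. Without HCT116, MT1A lost its call and HIST1H4I was not tested.

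Neuronal genes were higher in 20 of 25 cases, with a median log2 change of 2.89 (adjusted p = 0.0034, adjusted p = 0.32 with an estimated correlation; 21 adjusted over the list alone). On ratios within a line, with a pseudocount of 1, the neuronal median was 1.34, 2.64 and 1.06 in MHCC97H, A549 and HCT116, below the fitted 2.89. SYT11, a synaptotagmin (chromosome 1, 155859567 to 155885199), rose from 1.29 ± 1.40 to 174 ± 117 CPM. VGF, a neuropeptide precursor (chromosome 7, 101162509 to 101169952), rose from 21.8 ± 26.2 to 1230 ± 1310 CPM. STMN2, a stathmin, was at least 38.6-fold higher over the floor of 3 reads, and CHGA, chromogranin A, rose by 5.60 ± 0.89, with 5.19 in A549, 0.36 in HCT116 and 0.18 in MHCC97H. Clustered protocadherins were higher in 14 of 43 cases, with a median of 1.25 (adjusted p = 0.0014, adjusted p = 0.33 with an estimated correlation; 10 adjusted over the list alone), led by PCDHB18 (4.80), PCDHA1 (4.24), PCDHB12 (3.22) and PCDHB7 (3.05). Cancer-testis genes had positive values for 19 of 20 members but 1 call in each direction, GAGE1 (2.31) and MAGEA3 (-0.57), and the list passed with a median of 0.72 (adjusted p = 0.0029, adjusted p = 0.41 with an estimated correlation; 0 adjusted over the list alone). Among developmental regulators known as Polycomb targets, 6 of 24 were higher and 1 lower, with a median of 0.38 (adjusted p = 0.0079, adjusted p = 0.41 with an estimated correlation; 6 higher and 0 lower adjusted over the list alone). WNT1 was at least 11.2-fold higher over the floor of 3 reads, HAND1 rose by 4.40 and NKX6-1 by 2.72, while TBX15 fell by 2.66 (adjusted p = 0.0467 over all genes). Of the 3 keratin-associated proteins tested, KRTAP3-1 (7.62) and KRTAP4-12 (at least 19.5-fold) passed, with a median of 7.12 as fitted and 4.28 with the unseen member at its bound (adjusted p = 0.0079, adjusted p = 0.41 with an estimated correlation; 3 adjusted over the list alone). Without A549 no gene of this paragraph kept its call, with SYT11 and VGF at adjusted p = 0.0577 each, and CHGA, HAND1, WNT1, PCDHA1, PCDHB12 and PCDHB18 were not tested. PCDHB7 lost its call without each line, with log2 changes of 7.11, 2.61 and 2.51 without MHCC97H, A549 and HCT116. Without MHCC97H, HAND1, NKX6-1 and MAGEA3 lost theirs, and GAGE1, KRTAP4-12, PCDHB12, STMN2, TBX15 and WNT1 were not tested. Without HCT116, TBX15 lost its call, and KRTAP4-12, NKX6-1, PCDHB18 and STMN2 were not tested. Without A549 the neuronal, protocadherin and Polycomb lists stood at adjusted p = 0.082, 0.069 and 0.056. Without MHCC97H the protocadherin, cancer-testis and Polycomb lists stood at 0.057, 0.08 and 0.17, and the Polycomb list stood at 0.05 without HCT116. The medians in this paragraph are not set against other genes of low level: the 3387 genes in the lowest 20% by untreated level had a median of 1.15 under TSA, 0.22 under GSK126 and 0.23 under S2101, values that choosing genes by that level can itself raise.

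Stress and signalling genes formed the next groups. Of the p53 target genes 10 of 20 rose, with a median log2 change of 0.70 (adjusted p = 0.0013, adjusted p = 0.24 with an estimated correlation; 11 higher and 1 lower adjusted over the list alone). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676463 to 36687332), went from 72.8 ± 62.0 to 458 ± 199 CPM (log2 change 2.90 ± 0.45, adjusted p = 0.0027). TP53INP1 rose by 2.65, the secreted factor GDF15 by 2.30 and BBC3, which encodes the pro-apoptotic protein PUMA, by 2.08. Immediate early genes rose in 9 of 14 cases, with a median of 1.99 (adjusted p = 0.0096, adjusted p = 0.41 with an estimated correlation; 10 adjusted over the list alone), among them EGR3 (3.19), NR4A1 (3.14), EGR2 (2.67) and FOS (2.44). Autophagy and lysosome genes had 10 members higher and 2 lower of 20, with a median of 0.60 (adjusted p = 0.0079, adjusted p = 0.41 with an estimated correlation; 11 and 2 adjusted over the list alone). ATP6V0D1, a subunit of the vacuolar proton pump, rose from 47.1 to 163 CPM, and MCOLN1, a lysosomal ion channel, rose by 1.76. Interferon-stimulated genes had 7 members higher and 1 lower of 17, with a median of 0.63 (adjusted p = 0.016, adjusted p = 0.41 with an estimated correlation; 7 and 1 adjusted over the list alone), led by BST2 (4.33), IFI6 (3.66), IRF7 (3.20) and OASL (3.01). Without A549 no gene of this paragraph kept its call, with CDKN1A at adjusted p = 0.0659, BST2 at 0.173 and FOS at a log2 change of 1.58. Without MHCC97H, BST2 (log2 change 2.78, adjusted p = 0.179), BBC3, EGR2, FOS, GDF15, IRF7 and OASL lost theirs, and CDKN1A kept its call at a log2 change of 2.14. Without HCT116, EGR2 lost its call, EGR3 was not tested and BST2 stood at 6.52. Without A549 the immediate early, autophagy and interferon lists stood at adjusted p = 0.16, 0.064 and 0.16. Without MHCC97H the autophagy and interferon lists stood at 0.051 and 0.17, and without HCT116 the immediate early list stood at 0.072.

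Some markers of fibroblast, endothelial, myeloid and lung cells also rose under TSA, while most members of these lists did not pass. Of 7 fibroblast and endothelial markers 3 were higher, with a median of 1.92 (adjusted p = 0.0012, adjusted p = 0.41 with an estimated correlation; 3 adjusted over the list alone), namely PDGFRA (3.53), PDGFRB (3.04) and VWF, the von Willebrand factor (2.89). Of 7 genes known to rise in myeloid cells under LSD1 inhibitors, IRF8 (5.14) and CSF1R (5.0) passed, with a median of 1.32 (adjusted p = 0.0014, adjusted p = 0.41 with an estimated correlation; 2 adjusted over the list alone). Of only 3 blood cell markers tested, 2 were higher, also adjusted over the list alone, with a median of 4.62 (fry adjusted p = 0.008, adjusted p = 0.41 with an estimated correlation). Of these 2, HBA1, an alpha globin gene, rose by 6.11 ± 0.86 (adjusted p = 0.0752 without A549). Its level stayed low, at 2.13 ± 1.75 CPM, and is uncertain because it has a near-identical copy. PDGFRA and PDGFRB were low as well. In MHCC97H, A549 and HCT116 under TSA, PDGFRA stood at 1.5, 2.16 and 0.403 CPM and PDGFRB at 1.37, 0.81 and 2.35. Of 5 lung epithelium markers, LAMP3 (3.80) and ABCA3 (2.15) passed, with a median of 1.64 (adjusted p = 0.0048, adjusted p = 0.41 with an estimated correlation; 2 adjusted over the list alone). Without A549 the fibroblast, myeloid and lung lists stood at adjusted p = 0.056, 0.056 and 0.072, and without HCT116 the lung list stood at 0.05. Without A549 no gene of this paragraph kept its call, and IRF8 and PDGFRA were not tested. IRF8, LAMP3, PDGFRA (log2 change 2.32), PDGFRB and VWF lost theirs without MHCC97H, and PDGFRA, PDGFRB and VWF without HCT116.

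Genes of the cell cycle fell under TSA. Of 22 genes of S phase and DNA replication 16 were lower, with a median log2 change of -1.11 (adjusted p = 0.017, adjusted p = 0.41 with an estimated correlation; 16 lower and 1 higher adjusted over the list alone). TYMS fell from 159 ± 59.8 to 16.9 ± 14.6 CPM, and the replicative helicase genes MCM5 (-2.03), MCM3 (-1.91) and MCM4 (-1.75) fell with it. Of 20 genes of G2 and mitosis 14 were lower, with a median of -1.44 (adjusted p = 0.03, adjusted p = 0.45 with an estimated correlation; 17 adjusted over the list alone), including CCNA2, cyclin A2 (-2.66), CDK1 (-1.93), AURKA (-1.84) and UBE2C (-1.84). Heat shock genes had 6 members lower and 2 higher of 15, with a median of -0.50 (adjusted p = 0.0014, adjusted p = 0.32 with an estimated correlation; 7 and 2 adjusted over the list alone). The cytosolic chaperone HSPH1 fell by 2.25 ± 0.15. HSPE1 and HSPD1, the mitochondrial chaperonins, fell by 1.93 ± 0.16 and 1.48 ± 0.14, and HSPD1 went from 1480 ± 44.3 to 529 ± 62.4 CPM. DNAJB1, a cytosolic co-chaperone in the same list, rose by 1.43. Of the genes in this paragraph, HSPH1 alone kept its call without A549 (adjusted p = 0.0374), with HSPD1 at 0.0593 and TYMS at 0.0609. CDK1, UBE2C and DNAJB1 lost theirs without MHCC97H. The S phase list stood at adjusted p = 0.056, 0.064 and 0.16 without MHCC97H, A549 and HCT116, the G2 and mitosis list at 0.14, 0.083 and 0.15, and the heat shock list at 0.056 without A549 and 0.05 without HCT116.

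The transcripts of the compounds' targets moved by less. HDAC3 rose by 1.12 ± 0.28 (adjusted p = 0.0163) and HDAC2 fell by 0.63 ± 0.14 (adjusted p = 0.00995), while HDAC1 had a log2 change of 0.15 (adjusted p = 0.51), EZH2 -0.49 (0.142) and KDM1A -0.31 (0.146) in edgeR's quasi-likelihood test. Without MHCC97H the adjusted p of HDAC2 was 0.145 and that of HDAC3 0.149, and without A549 they were 0.134 and 0.163. Over 22 chromatin targets and partners, 4 were higher and 5 lower, with adjusted p = 0.45 for the list and the same counts adjusted over the list alone. HDAC7 fell by 2.21, and the demethylase genes KDM1B and KDM6B rose by 1.72 and 1.15. The 3 lost their calls without A549 and without MHCC97H, and without HCT116 KDM6B lost its call and HDAC7 stood at -3.4.

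Many lists did not pass fry's directional test under TSA. Cholesterol synthesis genes went both ways, with 5 higher and 3 lower of 23 (median 0.34, adjusted p = 0.4). INSIG1 (3.54 ± 0.70) and IDI1 (2.09 ± 0.56) rose, ACAT2 fell by 0.92, and the median of the list was 0.57 in MHCC97H, 0.70 in A549 and -0.36 in HCT116. Fatty acid synthesis genes also split, with SREBF1 (2.72) higher and ELOVL6 (-1.81) and FADS2 (-1.61) lower, 3 each way of 13 (adjusted p = 0.6). ATF4 target genes had 7 lower and 1 higher of 21 (median -0.68, adjusted p = 0.07), with TRIB3 (-2.54) and STC2 (-1.94) beside SLC7A11, and NRF2 target genes 6 lower of 18 (median -0.41, adjusted p = 0.09). Of 83 ribosomal protein genes 27 fell and 2 rose (median -0.27, adjusted p = 0.09). Glycolysis genes had 3 higher and 6 lower of 14 (adjusted p = 0.38), with ALDOC at 3.98 and ENO1 at -1.12. Mesenchymal genes had 4 higher and 1 lower of 18 (adjusted p = 0.32), among them COL1A1 (3.62) and SNAI2 (2.29), and epithelial genes 1 higher and 2 lower of 16 (adjusted p = 0.46). BCL2 family genes had 4 higher and 1 lower of 12 (adjusted p = 0.22), with BIK at 3.41 and BID at -2.28. The counts of the lists in this paragraph were the same adjusted over the list alone. Without A549 no gene of this paragraph kept its call, and without MHCC97H SLC7A11, FADS2 and BID alone did, with BIK at 2.14 and COL1A1 at 2.36. SNAI2 stood at 1.2 without HCT116.

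Aryl hydrocarbon receptor targets had 3 higher and 1 lower of 7 (adjusted p = 0.07), with the cytochrome P450 gene CYP1A1 at 4.77 ± 0.78. Oxidative phosphorylation genes had 4 higher and 1 lower of 21 (adjusted p = 0.32), and NF-kB inflammatory genes 1 higher, CCL20 (4.33), and 2 lower, CXCL5 (-4.60) and NFKBIA (-1.19), of 15 (adjusted p = 0.59). The median of the NF-kB list was 0.22 and its mean -0.19. Hypoxia genes (2 higher and 1 lower of 18, adjusted p = 0.53), endoplasmic reticulum stress genes (1 and 2 of 18, adjusted p = 0.4), hepatocyte markers (1 and 2 of 11, adjusted p = 0.47) and colon epithelium markers (1 and 0 of 7, adjusted p = 0.32) did not pass. Nor did olfactory receptors (1 and 2 of 15, adjusted p = 0.75), taste receptors (0 of 5, adjusted p = 0.097) or zinc finger genes (37 and 44 of 467, adjusted p = 0.93). Adjusted over the list alone, hypoxia genes had 0 and 0, endoplasmic reticulum stress genes 0 and 1, hepatocyte markers 0 and 2 and zinc finger genes 20 and 20, and the other lists of this paragraph the same counts. CYP1A1, CCL20, CXCL5 and NFKBIA lost their calls without A549, CCL20 and NFKBIA without MHCC97H and NFKBIA without HCT116.

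**Figure D2:**
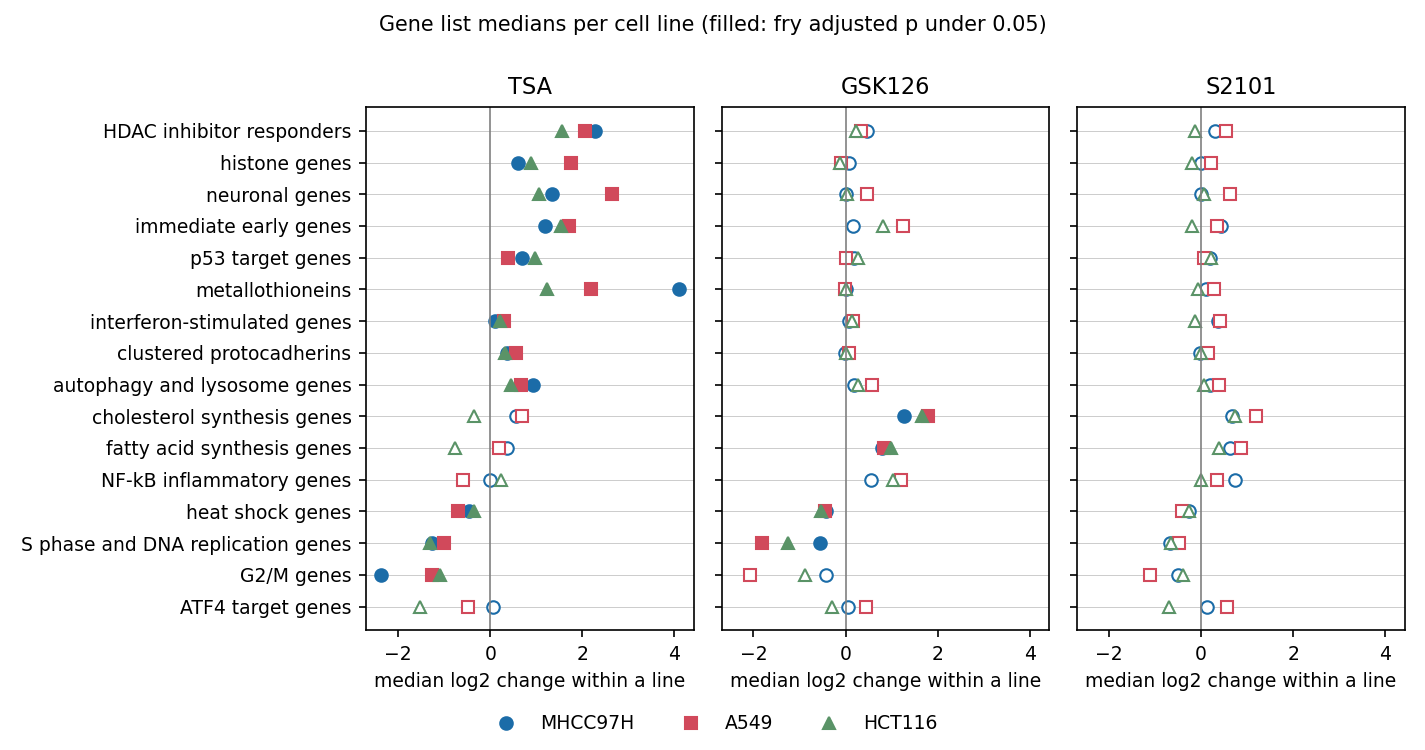
Median log2 change against the untreated library of each cell line (horizontal axes, shared scale) for a selection of the gene lists fixed beforehand, in 3 panels for TSA, GSK126 and S2101. Of all 39 lists tested, 19 passed fry under TSA, 4 under GSK126 and 0 under S2101. Under TSA the lists shown hold a larger share of passing lists than all 39. Each point is 1 cell line, filled where the list passed fry. Under TSA the histone genes had medians of 0.60, 1.75 and 0.88 in MHCC97H, A549 and HCT116, and under GSK126 the cholesterol synthesis genes 1.26, 1.78 and 1.66.

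Of 39 lists tested under TSA, 19 passed fry, and 0 passed camera with an estimated correlation, whose smallest adjusted p was 0.15. Camera with the preset correlation of 0.01 passed 15. The A549 libraries weighed most in these counts. Without A549, 12 genes and 4 lists passed under TSA, and 122 of the named genes lost their call, against 77 without MHCC97H and 16 without HCT116. Without MHCC97H the numbers were 1152 genes and 11 lists, and without HCT116 6495 genes and 14 lists. A lost call need not mean a smaller change. Without A549 the log2 changes of TYMS (-3.33) and SLC7A11 (-2.9) stayed near those of all 3 lines, while those of TXNIP (4.67) and FOS (1.58) fell. A fit on the 6 untreated and TSA libraries alone called 0 genes, with 5064 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0547, while DESeq2 called 6701.

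GSK126 was accompanied by higher expression of the enzymes that make cholesterol. All 23 listed genes of cholesterol synthesis and uptake had a value above 0 in each of the 3 lines. The list rose with a median log2 change of 1.59 (1.26 in MHCC97H, 1.78 in A549 and 1.66 in HCT116; adjusted p = 0.0095, adjusted p = 0.082 with an estimated correlation), and 23 members passed adjusted over the list alone against 0 over all genes. INSIG1, a sterol-regulated protein of the endoplasmic reticulum (chromosome 7, 155297878 to 155310235), went from 71.2 ± 37.3 to 374 ± 48.4 CPM. Fatty acid synthesis genes rose with a median of 0.89 (adjusted p = 0.029, adjusted p = 0.12 with an estimated correlation; 8 of 13 adjusted over the list alone). ACSS2, an acetyl-CoA synthetase (chromosome 20, 34874989 to 34927959), went from 29.7 ± 13.3 to 163 CPM with a log2 change of 2.53 ± 0.32 (adjusted p = 0.0605), and SCD, stearoyl-CoA desaturase, stood at 1200 ± 239 untreated and 4680 ± 2420 CPM treated.

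Heat shock genes fell as a group under GSK126, with a median log2 change of -0.49 (adjusted p = 0.0095, adjusted p = 0.082 with an estimated correlation; 8 of 15 lower adjusted over the list alone). HSPA4L (-1.01 ± 0.17) and HSP90AA1 (-0.95 ± 0.17, 3400 ± 956 to 1690 ± 187 CPM) had the largest values. S phase and DNA replication genes fell with a median of -1.17 (adjusted p = 0.039, adjusted p = 0.2 with an estimated correlation; 21 of 22 adjusted over the list alone), with GINS2 at -1.75 ± 0.26 and MCM4 at -1.54 ± 0.39. Genes of G2 and mitosis had values below 0 for each of 20 members and a median of -1.05 but did not pass (adjusted p = 0.15; 0 adjusted over the list alone). The next lists by p were aryl hydrocarbon receptor targets (median 0.81, adjusted p = 0.054), oxidative phosphorylation genes (-0.26, 0.069), cancer-testis genes (-0.37, 0.071), autophagy and lysosome genes (0.26, 0.08), NF-kB inflammatory genes (1.34, 0.084), immediate early genes (1.01, 0.089), p53 target genes (0.14, 0.089) and BCL2 family genes (0.31, 0.094). Adjusted over the list alone, 6 NF-kB, 4 immediate early, 4 autophagy, 2 BCL2 family and 1 aryl hydrocarbon receptor target gene were higher, 3 p53 targets were higher and 1 lower, and 0 oxidative phosphorylation and cancer-testis genes passed. The neutrophil chemokine gene IL8 had log2 changes of 4.13 in A549, 4.70 in HCT116 and 0.24 in MHCC97H, and WIPI1, an autophagy gene, 3.81, 2.14 and 1.42 in the same order. EZH2, the target of the compound, had a log2 change of -0.82 ± 0.24 (adjusted p = 0.143), KDM1A -0.46 and CDKN1A 0.92 ± 0.41 (adjusted p = 0.307). The developmental regulators known as Polycomb targets had a median of -0.06 (adjusted p = 0.89).

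No single gene passed under GSK126 in edgeR's quasi-likelihood test, where 2809 of 16929 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0605. The count differed between fits. DESeq2 called 1214 genes, a fit on the 6 libraries compared 434, and a fit on the 9 libraries without TSA 2114 (1040 higher and 1074 lower), the last chosen after the data were seen. RLE scaling, no low-count filter and a filter of 10 CPM each called 7, of which ACSS2, CYP51A1, DHCR7, LPCAT1, MVD and MXD4 were common to the 3 settings. These genes, named after their values were seen, had log2 changes of 1.37 to 2.55 with RLE scaling. The 4 passing lists went to 0 without MHCC97H (cholesterol synthesis adjusted p = 0.069) and to 0 without A549 (0.38). Without HCT116, 6 lists passed, among them cholesterol synthesis (0.029).

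**Figure D3:**
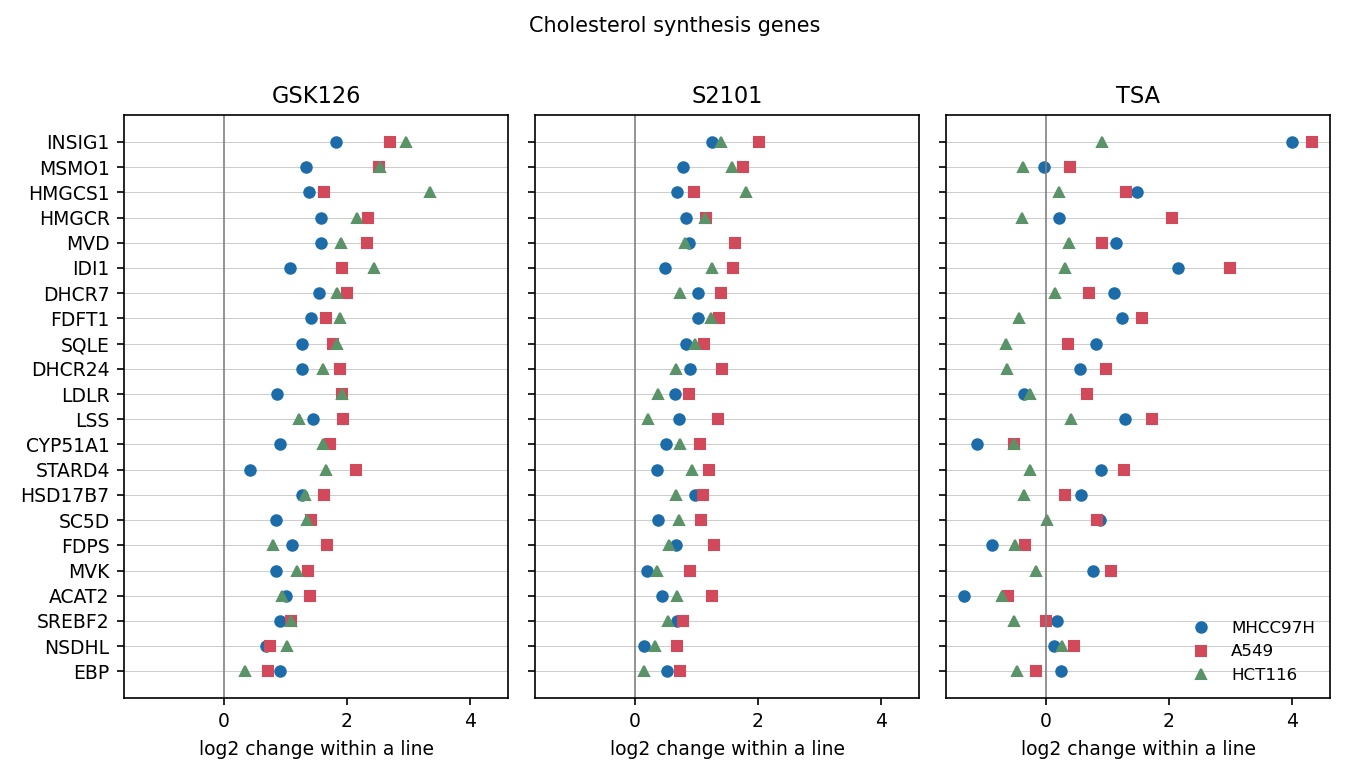
Log2 change within a line (horizontal axes) of cholesterol synthesis genes (vertical axis, 1 gene per line of the plot) under GSK126, S2101 and TSA, with MHCC97H in blue, A549 in red and HCT116 in green. All genes shown lie above 0 in the 3 lines under GSK126 and under S2101, and 8 do so under TSA.

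Under S2101 the cholesterol synthesis genes again lay on one side. All 23 were above 0 in each of the 3 lines, with medians of 0.68 in MHCC97H, 1.20 in A549 and 0.73 in HCT116. The list did not pass fry (median 0.97, adjusted p = 0.08), although 18 of 23 members passed adjusted over the list alone. MSMO1, a sterol methyl oxidase (chromosome 4, 165327669 to 165343164), stood at 73.0 ± 51.8 untreated and 171 ± 62.9 CPM treated (log2 change 1.38 ± 0.29, adjusted p = 0.939), and ACSS2 had a log2 change of 1.56 ± 0.31. Heat shock genes had a median of -0.34 (adjusted p = 0.08), fatty acid synthesis genes 0.62 (0.18; 4 adjusted over the list alone) and cancer-testis genes -0.28 (0.08). S phase genes had a median of -0.61 (adjusted p = 0.37), with RRM2, a ribonucleotide reductase subunit, at -1.09, and G2 and mitosis genes -0.70 (0.44), with values below 0 for each of the 22 and 20 members. KDM1A, the target of the compound, had a log2 change of -0.32 ± 0.15 (adjusted p = 0.939). Of the genes listed as LSD1 inhibitor responders in myeloid cells, 6 of 7 were above 0, with a median of 0.45 (adjusted p = 0.37). The histone deacetylase inhibitor responders had a median of 0.38 (adjusted p = 0.37) and TXNIP 1.11, 4.23 and 0.0 in MHCC97H, A549 and HCT116. Adjusted over the list alone, 0 members passed in the heat shock, cancer-testis, S phase, G2 and mitosis, myeloid and deacetylase inhibitor responder lists.

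No gene passed under S2101 in edgeR's quasi-likelihood test, with 852 at an unadjusted p under 0.05, and DESeq2 called 23. A fit on the 6 libraries compared called 25, and a fit without the TSA libraries and without the A549 S2101 library called 1, IGFBP1 (log2 change 3.69, adjusted p = 0.0262), a fit chosen after the data were seen. No list passed fry in any fit on all 3 lines. Camera with the preset correlation passed 20 and with an estimated correlation 0 (smallest adjusted p = 0.17). Without HCT116, 2 lists passed, epithelial genes (adjusted p = 0.0087) and interferon-stimulated genes (0.013).

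The A549 library treated with S2101 stood apart from the other S2101 libraries. Its 3 largest increases, DHRS2 (log2 ratio 4.50), TXNIP (4.23) and SLC17A7, a vesicular glutamate transporter (3.75), were also the 3 largest of A549 under TSA (8.09, 7.69 and 7.20). With a pseudocount of 0.1 the values under S2101 were 4.64, 5.53 and 4.85. All 29 genes switched on by S2101 in A549 were switched on by TSA in A549. For 22 genes under 0.1 CPM in untreated A549 and at least 15 CPM under TSA, the S2101 library held 7.72% of the TSA level, with 10th and 90th percentiles of 5.76 and 9.02%. The same measure was 2.08% in the A549 GSK126 library and 0.36 and 0.41% in the S2101 and GSK126 libraries of MHCC97H. Values under S2101 that rest on A549 are to be read with this level beside them.

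**Figure D4:**
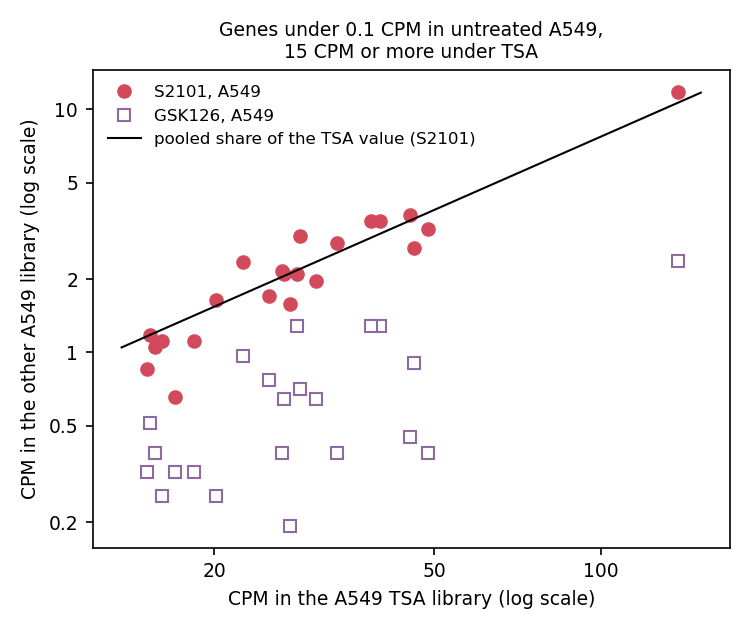
Level in the A549 S2101 (red points) and GSK126 (open squares) libraries (vertical axis, CPM, log scale) against the level in the A549 TSA library (horizontal axis, CPM, log scale) for genes under 0.1 CPM in untreated A549 and at least 15 CPM under TSA, 1 mark per gene and library. The red points lie around the drawn line at 7.72% of the TSA level and the squares, at 2.08%, below it.

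Tested against each other, TSA and GSK126 differed in 4901 genes (2490 higher and 2411 lower under TSA) and 21 lists. The histone genes (40 higher and 2 lower of 54, median 2.92, adjusted p = 0.0029, adjusted p = 0.27 with an estimated correlation), neuronal genes (19 of 25 higher, 2.45, 0.0033, likewise 0.27) and deacetylase inhibitor responders (13 of 16 higher, 1.95, 0.0013, likewise 0.22) were higher under TSA. Cholesterol synthesis genes were lower under TSA than under GSK126 in 14 of 23 cases (median -1.13, adjusted p = 0.0051, adjusted p = 0.27 with an estimated correlation). Fatty acid synthesis genes were lower in 7 and higher in 3 of 13 (-1.41, adjusted p = 0.0059, likewise 0.27), and NF-kB genes lower in 5 of 15 (-1.56, adjusted p = 0.03, adjusted p = 0.45 with an estimated correlation). Oxidative phosphorylation genes were higher in 8 of 21 (0.22, adjusted p = 0.0082, adjusted p = 0.5 with an estimated correlation). S phase genes had a median difference of -0.01 (adjusted p = 0.99). Adjusted over the list alone the counts were 41 and 2 for histone, 20 for neuronal, 14 for responder, 15 for cholesterol, 8 lower and 3 higher for fatty acid, 6 for NF-kB and 8 for oxidative phosphorylation genes. Without MHCC97H 1088 genes differed, and without A549 0, where 4193 had an unadjusted p under 0.05.

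TSA and S2101 differed in 4505 genes (2291 higher and 2214 lower under TSA) and 16 lists. Histone genes (39 higher and 2 lower of 54, median 2.78, adjusted p = 0.0022, adjusted p = 0.2 with an estimated correlation) and neuronal genes (17 of 25 higher, 2.47, 0.0031, likewise 0.2) were higher under TSA. Immediate early genes were higher in 5 of 14 (1.63, adjusted p = 0.029, adjusted p = 0.46 with an estimated correlation), and fatty acid synthesis genes lower in 5 and higher in 2 of 13 (-0.64, adjusted p = 0.03, likewise 0.46). Cholesterol genes were lower in 8 of 23, and the list did not pass (-0.38, adjusted p = 0.063). Adjusted over the list alone the counts were 42 higher and 3 lower for histone, 19 for neuronal and 6 for immediate early genes, 5 lower and 2 higher for fatty acid genes and 8 lower and 1 higher for cholesterol genes. Without MHCC97H 0 genes differed, with 4245 at an unadjusted p under 0.05, without A549 17 and without the A549 S2101 library 1926.

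GSK126 and S2101 differed in no gene in edgeR's quasi-likelihood test, with 470 at an unadjusted p under 0.05. DESeq2 called 3, HSPA4L (log2 difference -0.81, adjusted p = 0.0443), HEPACAM2 and TRIM49C, the latter pair with unstable fitted sizes. The cholesterol genes were higher under GSK126 than under S2101 in 23 of 23 cases, with a median difference of 0.68 that did not pass (adjusted p = 0.5; 5 members adjusted over the list alone). S phase genes had a median difference of -0.54 (adjusted p = 0.5). Of 39 lists 0 passed fry, 11 passed camera with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.32).

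Across genes, which are not independent replicates, the log2 changes under TSA correlated with r of 0.73 between MHCC97H and A549, 0.42 between MHCC97H and HCT116 and 0.48 between A549 and HCT116. Under GSK126 the values were 0.53, 0.37 and 0.52, and under S2101 0.42, 0.24 and 0.20. One direction in all 3 lines was seen for 54.8% of genes under TSA, 44.9% under GSK126 and 38.9% under S2101, where chance gives 25%. Changes were fewer in HCT116 under TSA, with 1444 genes at least 2-fold changed against 3651 in MHCC97H and 3837 in A549, a difference between lines that was not tested.

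The 3 comparisons share the untreated libraries. For changes averaged over the 3 lines, GSK126 and S2101 correlated with r of 0.828, where simulated unchanged groups sharing those libraries gave 0.504. Within MHCC97H, A549 and HCT116 r was 0.808, 0.752 and 0.627, against 0.502, 0.503 and 0.497 simulated. A simulated r near 0.5 follows from setting unchanged groups against the same control, whatever the spread. The covariance of the averaged changes was 0.095 against 0.051 simulated, and within the lines 0.118, 0.215 and 0.098 against 0.146, 0.16 and 0.146, above the simulated value in A549 alone. With the spread of the 9 libraries without TSA, the simulated covariances were 0.055, 0.059 and 0.055. For TSA and GSK126 the averaged changes had r of 0.327 (0.5 simulated) and a covariance of 0.117 (0.05 simulated), and the covariance within lines was 0.136, 0.29 and 0.079 against 0.148, 0.159 and 0.147. For TSA and S2101 r was 0.441 (0.503 simulated), the covariance of the averaged changes 0.106 (0.051 simulated) and that within lines 0.117, 0.307 and 0.041 against 0.148, 0.161 and 0.147. With the spread of the 12 libraries, the averaged covariance thus exceeded the simulated value in both pairs with TSA. Within lines A549 alone did so. These pairs were simulated with that spread only, which takes in differences between lines under TSA. For GSK126 and S2101 that spread gave higher simulated covariances than the 9 libraries did. The comparison within MHCC97H and HCT116 therefore decides nothing for the pairs with TSA. Nor do their r values below the simulated 0.5, since changes under a single compound can lower r however the libraries are shared. In DESeq2, 208 genes were higher and 435 lower under both TSA and GSK126, with 69 opposite, where independent lists share 106.9 and 163.6. TSA and S2101 shared 12 higher and 4 lower genes with 3 opposite (3.6 and 1 for independent lists), and GSK126 and S2101 19 and 4 with 0 opposite (0.9 and 0.2). The overlaps in edgeR were 0 because GSK126 and S2101 had no calls. Each line has 1 untreated library, so the controls could not be divided, and overlaps beyond those of independent lists are open to that sharing.

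Some of the largest changes within a line recurred in another line. DHRS2 had the largest increase under TSA in A549 (log2 ratio 8.09) and in HCT116 (6.58), and IL8 was among the 3 largest increases under GSK126 in A549 (4.13) and HCT116 (4.70), or 4.9 and 5.81 with a pseudocount of 0.1. PEG10, an imprinted retrotransposon-derived gene (chromosome 7, 94656325 to 94669695), went from 10.7 to 2140 CPM in MHCC97H under TSA, where the tight junction gene CLDN2 went from 282 to 4.04. HCT116 showed LINC00659 (0.996 to 114 CPM) and VGF (51.9 to 2750) among the increases under TSA, and CHAC1 (56.3 to 2.89), DDIT4 (409 to 41.3) and PSAT1 (log2 ratio -2.95) as the largest decreases. Under GSK126, STC1, stanniocalcin, went from 19.3 to 407 CPM in A549 and AMOTL2 from 174 to 12.2, while FGFBP1 went from 1.58 to 33.8 in HCT116 and AQP2 from 8.43 to 67.2 in MHCC97H. Under S2101, IGFBP1 went from 63.6 to 787 CPM and BIRC3 from 19.9 to 174 in MHCC97H, and CHAC1 from 56.3 to 5.27 in HCT116. These ratios compare 2 libraries each and have no replicate check.

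Lineage markers were read in the untreated libraries. KRT20, an intestinal keratin, stood at 1030 CPM in MHCC97H, 1.21 in A549 and 0.368 in HCT116, LGALS4 at 148, 0.575 and 0.0614, CDH17 at 119, 8.95 and 0.184, and VIL1, villin, at 24.0, 0.0639 and 0.123. CDX2, an intestinal transcription factor named outside the fixed rule, stood at 3.68, 0.575 and 12.6 CPM. HNF4A, a transcription factor of liver and gut, stood at 52.0, 28.7 and 9.21 CPM, APOB at 13.6, 0 and 0, and ALB, albumin, at 0.499 in MHCC97H. ABCA3, a lipid transporter of the lung, stood at 2.43, 36.1 and 9.58 CPM. Of the other lung markers, SFTPB stood at 2.0, 1.73 and 1.9 CPM, LAMP3 at 0.562, 0.383 and 5.16, and NKX2-1 at 0, 0 and 1.6. ABCA3 alone among these was highest in A549.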

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

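The tests of explanations, the other divisions of the libraries and the fit without the TSA libraries were chosen only after the result was seen.

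The median log2 change of epithelial genes under TSA lay on opposite sides of 0, at 0.69 in MHCC97H and 0.59 in A549 against -0.54 in HCT116. The list did not pass (adjusted p = 0.46), nor did 13 of its 16 genes, and the difference between lines was not tested. The median of ATF4 target genes under S2101 was 0.13 in MHCC97H, 0.57 in A549 and -0.70 in HCT116, where 0 of 21 genes passed, the list had adjusted p = 0.99, and the difference was also untested.

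The first pattern is the larger number of detected genes under TSA in all 3 lines, 1408.3 ± 281.0 (SD, n = 3). Thinning the libraries to one total left a gain of 1349.3 genes and TMM scaling 1128.3, which argues against library size and against the scaling of CPM as the whole cause. An even background of reads, set by olfactory receptors with 0 reads in untreated cells, would switch on at most 0.00065 genes in a line, where 144 to 480 were seen. A broad opening of silent genes by TSA remains a hypothesis that may account for the gain. Handling common to all treated cultures would give GSK126 and S2101 like gains, but in each line the gain under TSA was larger than theirs by at least 930 genes, which argues against it as the whole cause, while handling of the TSA cultures alone stays open with 1 library per line and condition and no vehicle-treated culture.

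The second pattern is the profile of TSA at a low level in the A549 library treated with S2101. A response to S2101 like that to TSA would also lower the genes that TSA lowers, but the 100 genes at least 8-fold lower under TSA had a median log2 change of -0.11 under S2101, close to the -0.12 that a share of 7.72% of TSA reads allows at most. A share of reads or RNA from the A549 TSA library needs one constant level for all genes, and the 22 silent genes scattered around one share with a chi-square per gene of 1.25, against 2.50 in the A549 GSK126 library. Carry-over between the 2 libraries is a candidate explanation, and a small part of the cells responding fully as to TSA would look the same and stays open.

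The third pattern is that changes under GSK126 and S2101 go together, with 23 of 23 cholesterol synthesis genes above 0 in each line under both. The shared untreated libraries are not the whole cause, because GSK126 in one line and S2101 in another share no library and still correlated with a mean r of 0.36 (0.21 to 0.56) without the A549 S2101 library. Handling common to all treated cultures would also tie TSA to both compounds, and the mean covariance across lines was 0.09 (0.026 to 0.214) for TSA and GSK126 and 0.042 (0.011 to 0.095) for TSA and S2101, against 0.074 (0.027 to 0.14) for GSK126 and S2101. These values lie on either side and their ranges overlap, so they do not decide it. A stress or sterol response common to 2 small molecules at 50 and 100 µM, and effects of a vehicle, may each account for it and were not tested.

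Dividing the 6 libraries of a contrast in 10 ways gives too few divisions for a share under 0.05, since the smallest is 0.1. Each division except the real one puts libraries of both conditions in both groups. A difference between the conditions then adds to the spread and lowers the count. The gap between the real count and the others therefore does not measure how far a change recurred between lines. The real division called 5851 genes for TSA against at most 2 in the others, 4901 against 2 for TSA and GSK126, and 4505 against 1 for TSA and S2101. For GSK126, S2101 and their difference, each of the 10 divisions called 0 genes, the real one included, and for GSK126 without the TSA libraries the real division called 2114 and the others 0. Lists passing were 19 against 0 for TSA, 4 against 0 for GSK126, and 0 in all 10 for S2101. In 1 of the 10 divisions, the real one, the TSA counts were as large as observed. The highest other count came from a division that also parts all 3 pairs but moves HCT116 to the other side, 1 of 4 such divisions.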

How the results depend on the processing

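Settings chosen only after the results were seen are the fits on 9 and 8 libraries, the fit without the A549 S2101 library and the overlap in DESeq2. RLE scaling moved no count of TSA calls by 1.5 times (5822), and the 19 lists passing under TSA kept their side of the threshold with it. The median log2 change of all tested genes under TSA was 0.078, and 0.114 with RLE scaling on the same 16929 genes, so changes of that size are not told from scaling. It was 0.212 without the low-count filter, over 22529 genes, and 0.252 in DESeq2. These fits cover other sets of genes, so their medians do not speak of scaling alone. A pseudocount of 0.1 applies to ratios within lines, not to the count test, and moved 25 of 54 ratios by at least 0.2. No result changed its direction past the threshold. With 3 reads at 0.157 to 0.207 CPM, silence in untreated cells means a level under that floor.

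The pairing by cell line mattered. With no replicate block, 260 genes changed under TSA, 14 differed between TSA and GSK126 and 0 between TSA and S2101 (2474 at an unadjusted p under 0.05), and 1 list passed under TSA and 1 under GSK126. The count of genes stayed at 0 without the block for GSK126, S2101 and their difference.

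Leaving out a line gave 12 to 6495 genes under TSA, 0 to 5496 between TSA and GSK126 and 0 to 5144 between TSA and S2101. Lists passing were 4 to 14 under TSA, 0 to 6 under GSK126 and 0 to 2 under S2101. Genes switched on in all lines were 31 to 110 (14 in 3 lines), and genes switched on per line had a mean as low as 5.0 under GSK126 and 2.0 under S2101 without A549. Among the named genes, 122 lost their call without A549, 77 without MHCC97H and 16 without HCT116. The cause was not tested.

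Without the A549 S2101 library, 1926 genes differed between TSA and S2101, 2 lists passed under GSK126 and 17 under TSA, and the mean of switched-on genes under S2101 was 2.0. GSK126 changed 7 genes with RLE scaling, 7 without the low-count filter and 7 at 10 CPM, 434 in the 6 libraries compared, 2114 in 9 libraries, 1161 in 8 libraries and 1214 in DESeq2; the cause was not tested. S2101 changed 25 genes in the 6 libraries, 1 in 8 libraries and 23 in DESeq2, and DESeq2 gave 3 for GSK126 against S2101. The fits on 6 libraries called 0 genes for TSA, 164 for TSA against GSK126 and 0 for TSA against S2101 (4647 at an unadjusted p under 0.05; DESeq2 5502); the cause was not tested.

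A detection threshold of 5 CPM gave 725.3 more genes under TSA. Switched-on genes per line (367.0, 9.7 and 11 for TSA, GSK126 and S2101) became 219.3, 3.3 and 4.7 with 0 reads required in the untreated library and 61.3, 0.3 and 0.3 with 5 CPM required after treatment, and those in all 3 lines under TSA 7 and 1. The mean correlation between lines under GSK126 (0.47) was 0.56 at 10 CPM and 0.34 with a pseudocount of 0.1, and that under S2101 (0.29) 0.35 and 0.19. DESeq2 gave overlaps of 643 genes for TSA and GSK126, 16 for TSA and S2101 and 23 for GSK126 and S2101. Camera with the preset correlation passed 15 lists under TSA, 11 under GSK126 and 20 under S2101, and with an estimated correlation 0, 0 and 0. Except where the construction of a setting shows it, the cause was not tested.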

Other observations

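The values in this part were singled out only after they were seen, and no further test was made on them.

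ABCC3 fell under TSA in each line, with log2 ratios of -4.02, -3.46 and -1.92 in MHCC97H, A549 and HCT116, while in HCT116 it went from 18.0 to 122 CPM under S2101. Of 21 oxidative phosphorylation genes, a list that did not pass under TSA (median 0.01), 1 fell and 4 rose, the latter with log2 changes of 1.23 ± 0.17 for NDUFA2, 0.96 ± 0.18 for SDHA, 0.90 ± 0.17 for NDUFB3 and 0.87 ± 0.17 for NDUFV1, whereas NDUFB3 had -0.55 ± 0.17 under GSK126 (adjusted p = 0.15 in edgeR's quasi-likelihood test). XBP1, a transcription factor of the unfolded protein response, fell by 1.60 ± 0.31 under TSA and CALR, calreticulin, rose by 0.67 ± 0.22. Of the zinc finger genes, ZNF80 went from 1.89 ± 0.498 to 90.7 ± 85.4 CPM and rose in each of the 3 lines. Without A549 these genes lost their calls under TSA, and without MHCC97H NDUFB3, SDHA, XBP1 and CALR did.

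ATF4 targets had their lowest median under TSA in HCT116, at -1.53, with -0.49 in A549 and 0.07 in MHCC97H. In HCT116 the 3 largest decreases under TSA, CHAC1, DDIT4 and PSAT1, all belong to that list, and CHAC1 and SESN2 were among the 3 largest decreases under S2101. HCT116 was grown in another medium than the other lines.

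Of 10 intestinal markers, 5 were higher in untreated MHCC97H than in HCT116, with KRT20 at 1030 and 0.368 CPM, LGALS4 at 148 and 0.0614, CDH17 at 119 and 0.184, VIL1 at 24.0 and 0.123 and CEACAM5 at 20.2 and 0.921. CDX2 was lower, at 3.68 and 12.6, GPA33 stood at 0.0624 (below the level of 3 reads) and 0.368, and CDX1, MUC2 and PHGR1 were at 0 in both. Albumin stood at 0.499 CPM in MHCC97H. The identity of the lines was not tested here.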
